A study of Ovis aries with 20 samples.

How the data were processed

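Pregnant ewes received 100 mg testosterone propionate (1.2 mg/kg) or vehicle by intramuscular injection 2 times per week from day 30 to day 90 of gestation. Ovaries of the adult offspring were taken at 21 months, 18 h after the last of 2 injections of 10 mg prostaglandin F2 alpha given 11 days apart. Granulosa and theca cells of several antral follicles per animal were microdissected from cryosections of 14 µm on membrane slides and pooled by layer, and total RNA was made into stranded libraries after removal of ribosomal RNA. The animals were controls 139, 224, 244, 246 and 268 and prenatal T sheep 209, 210, 230, 276 and 315. Planning assumed 20 libraries. The table held 19, without granulosa cells of control sheep 139, which were not analysed here, and 0 columns of values lacked a sample.

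The deposited table holds a signal per gene and library, the gene count that the authors divided by a size factor of the library. FastQC 0.11.5, MultiQC 0.9, STAR 2.6.0c, featureCounts of Subread 1.6.1 and DESeq2 are named per the submitters' processing notes. The genome build is not given in the sources used here, and no coordinates were used. In each library 100% of values were whole multiples of 1 step (relative tolerance 1e-06), so whole reads were recovered, at 12.7 to 26.0 M per library. The table has 28524 genes, 24823 above 0 in some library. A RefSeq gene table of sheep assembly ARS-UI_Ramb_v3.0 served for names and gene types only: of 10441 LOC identifiers 6969 were matched by gene ID and 406 given a symbol. Intervals from read depth hold counting error only, and the spread between animals is given by the SD or SE.

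Pairing was checked on deviations from group means: layers of an animal correlated at r = 0.42 to 0.80 across genes, which are not independent replicates. The own other layer matched best in 9 of 9 animals (0.57 against 0.53 in sheep 230). Libraries of the same group were checked for repeats of 1 sample, and none was found (36 pairs, smallest chi-square per degree of freedom 27.7).

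Genes with a value of at least 10 in at least 5 libraries were tested by limma 3.58.1 (R 4.3.3) with a mean-variance trend on log2 of the value plus 1, for prenatal T against control in granulosa cells (4 controls, 5 prenatal T) and in theca cells (5 and 5), for the difference of these effects, and for granulosa against theca cells, the last 2 with the animal as a block. These tests were two-sided, and p was adjusted by Benjamini-Hochberg over the genes of a comparison at a threshold of 0.05. edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the recovered reads. Before the data were examined, 27 gene lists and 18 genes of follicular function were fixed, along with the comparisons. Lists with at least 5 tested members were tested by camera with a preset correlation of 0.01, again with an estimated correlation, and by fry of limma. The fixed genes were tested by exact permutation of the treatment over animals, with p adjusted over the 36 tests of both layers. The correlation of the layers' effects across genes was tested by reassigning treatment over whole animals. Further lists of general epithelium, neutrophils and reproductive tract glands were set down after the values of sheep 209 were seen.

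Genes were named by a rule. In each prenatal T comparison these are genes past the threshold (at most 10 up and 10 down, mean of at least 10) or, with fewer than 10, those of smallest unadjusted p up to 10 in all. For the difference of effects the rule takes the 5 of smallest p in each direction, and between layers the 10 largest changes in each direction among passing genes with a mean of at least 100. To these are added the fixed genes and up to 4 members of smallest p from each list called or holding a passing gene. Genes without a symbol are named only by identifier, and some genes that the rule selects are not reported here, nor counted among the settings tried. The rule was applied to all libraries and again without sheep 209.

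The tests were run on simulated data with the dispersions of these libraries and known changes of 1.5, 2, 4 and 8-fold, without simulating effects of the animal. The shares of changed genes that limma called were, in that order, 0, 2.04, 50.0 and 73.9 percent in granulosa cells, 0, 18.4, 74.0 and 81.2 percent in theca cells, 2.00, 22.0, 51.0 and 84.0 percent for the difference of effects and 39.6, 68.0, 92.0 and 98.0 percent between layers. With dispersions without sheep 209 they were 2.04, 19.1, 68.9 and 100.0 percent, 4.00, 43.8, 91.8 and 95.8 percent, 6.00, 42.9, 86.0 and 82.0 percent and 63.3, 76.0, 98.0 and 100.0 percent. Unchanged genes called by limma were 2 in granulosa cells, 4 in theca cells, 3 for the difference of effects and 8 between layers, and by DESeq2 39, 45, 36 and 43. With dispersions without sheep 209 DESeq2 called 35, 41, 30 and 36. The runs held changed genes too, so real counts cannot be set against these numbers. In these runs, which hold no correlation between genes, a list of 30 genes changed 2-fold was called each time and 0 of 25 unchanged lists were. Random regroupings of the real libraries called a median of 11 lists in granulosa cells, 12 in theca cells and 10 between layers at the preset correlation.

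Alternatives set down in advance were pseudocounts of 0.5 and 5, no filter, a mean of at least 50, rescaling to equal totals, quantile normalization, sample quality weights, robust variances, a threshold of 0.1, 1 model of all libraries, no animal block, 1 treatment group only, covariates for markers of the other layer and for the share of genes detected, and leaving out each animal. After the data were seen, the following were added: edgeR and DESeq2 without sheep 209, leaving out sheep 209 and 315 together, the covariate of other-layer markers without sheep 209, and the correlation across genes without sheep 209. Further software was the R package data.table at version 1.17.8, Python 3.11.15 and matplotlib 3.10.9. Mitochondrial genes were left out, as none of the list was matched in the table, and samples outside the 19 libraries were not used here.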

Results

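Granulosa cells, which line the follicle and make estradiol, and theca cells, which surround them and make androgen, were collected from antral follicles of adult sheep. Of 10 animals, 5 came from ewes given testosterone propionate in gestation (prenatal T animals) and 5 from ewes given vehicle (controls). RNA sequencing counts of 19 libraries were used. They were granulosa cells of 4 controls and 5 prenatal T animals and theca cells of 5 controls and 5 prenatal T animals. The granulosa sample of control sheep 139 was not analysed here. Recovered reads per library (mean ± SD) were 19.8 ± 5.25 M in control granulosa (n = 4), 14.2 ± 1.38 M in prenatal T granulosa (n = 5), 15.9 ± 1.48 M in control theca (n = 5) and 14.7 ± 0.582 M in prenatal T theca (n = 5). The comparison of prenatal T with control animals asks which genes of each follicular layer differ in adult life after exposure to testosterone before birth. The comparison of layers asks which genes separate granulosa from theca cells. Levels are normalized counts, given as mean ± SD with n as above unless stated. Changes and list medians are log2 values of prenatal T minus control, or granulosa minus theca, given ± SE of the limma fit.

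Both libraries of prenatal T sheep 209 had low levels of follicle markers, several of them at 0. AMH, the anti-Müllerian hormone of granulosa cells, stood at 0 in its granulosa library of 16.1 M reads and at 2629 to 7774 in the other 8. FSHR, the receptor of follicle-stimulating hormone, stood at 0 against 1105 to 3281, and INHA, the inhibin alpha subunit, at 8.05 against 7238 to 38080.4. In its theca library CYP17A1, the enzyme that makes androgen precursors, stood at 0 against 585 to 2523 in the other 9, and INSL3, a peptide hormone of theca cells, at 1.27 against 3546 to 18648. Other theca markers were reduced there, such as COL1A1 at 127254 against 250557 to 427685, and the mean log2 value of the theca marker list was 10.17 against 11.87 to 12.30. Across genes, the log2 values of sheep 209 correlated with those of the other granulosa libraries at r = 0.63 to 0.74, where the other pairs reached 0.91 to 0.97. In theca the range was 0.74 to 0.80 against 0.92 to 0.97, and genes are not independent replicates in either range. Most results are therefore given with all libraries and without sheep 209. Leaving out each animal had been planned for limma and the gene lists, while edgeR, DESeq2 and the correlation across genes without sheep 209 were chosen after the data were seen.

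In granulosa cells FGD5, an exchange factor for the GTPase Cdc42 known from blood vessel growth, had the smallest p of the prenatal T comparison, at 519 ± 176 in controls and 161 ± 27.1 in prenatal T animals, a log2 change of -1.64 ± 0.24. The matrix protein CCN3, which the table holds as separate entries CCN3_1 and CCN3, stood at 955 ± 795 against 86.3 ± 37.7 (-3.23 ± 0.54) and 1983 ± 1733 against 204 ± 85.5 (-3.04 ± 0.58). SH3D21 stood at 672 ± 312 against 137 ± 74.1 (-2.34 ± 0.45), and EPHB4, a receptor tyrosine kinase for ephrin-B2, at 2100.4 ± 227 against 1329 ± 176 (-0.66 ± 0.13). SLC41A2, a magnesium transporter, was the sole gene of the 10 of smallest p with a higher level in prenatal T animals, at 118 ± 31.0 against 273 ± 67.0 (1.21 ± 0.28). The changes of the intramembrane protease SPPL3, TIGD5 and WDR73 were -0.72, -0.48 and -0.97. For each of these genes, all 5 prenatal T libraries lay on the same side of all 4 controls.

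None of these genes passed. The limma test called 0 of 14724 genes (smallest adjusted p = 0.875) with 622 at an unadjusted p under 0.05. edgeR called 0 (835 at an unadjusted p under 0.05). DESeq2, which called unchanged genes on simulated data too, called 16, 5 up and 11 down. Among them were FGD5 (adjusted p = 2.63e-06), CCN3_1 (7.79e-06), CCN3 (0.000167), SH3D21 (0.00495), EPHB4 (0.00532), and SLC41A2 (0.0158). The other genes called up, chosen after their values were seen, were ENOX2, NIFK, TMEM167A and the interferon gene IFIT3. With all libraries fitted in 1 model and the animal as a replicate block, limma called FGD5 alone (log2 change -1.69, adjusted p = 0.0140). Without sheep 209 the counts were 0 by limma (1013 at an unadjusted p under 0.05), 0 by edgeR and 32 by DESeq2 (5 up, 27 down). The 5 called up by DESeq2 were then PLEK, SLC41A2, CHI3L1, CLCN5 and ENOX2, of which all but SLC41A2 were chosen after their values were seen. Genes that entered the 10 of smallest p without sheep 209 were CTTNBP2, which binds cortactin (-1.73 ± 0.31, against -1.02 ± 0.76 with all libraries) and FBXW4 (-1.46 ± 0.26, against -1.02 ± 0.51). Others included LDLRAD4, a brake on TGF-beta signalling (-1.08 ± 0.21), and the palmitoyltransferase ZDHHC14 (-0.79 ± 0.16). FGD5 (-1.61 ± 0.25), CCN3_1 (-3.03 ± 0.52) and EPHB4 (-0.65 ± 0.13) were near their values with all libraries.

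An estimate of the share of theca RNA in the granulosa libraries was lower in value in prenatal T animals other than sheep 209 than in controls. The 100 genes highest in theca against granulosa cells, with the theca marker list left out, were set against their mean level in the theca libraries other than sheep 209. The median ratio was 7.02 ± 2.25% in controls (n = 4) and 4.43 ± 1.6% in prenatal T animals without sheep 209 (n = 4, two-sided exact permutation p = 0.143 on the log2 ratio). In the granulosa library of sheep 209 it was 9.48%.

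Of 25 gene lists fixed for this tissue, camera called 12 in granulosa cells, 7 up and 5 down, and 14 without sheep 209. With an estimated correlation 0 were called (smallest adjusted p = 0.464, and 0.445 without sheep 209). By fry, which tests whether a list's genes move on balance to 1 side, 0 were called (smallest adjusted p = 0.198). With all libraries 0 members of any list passed by limma, over all genes or adjusted over the list alone. Interferon response genes, which restrict viruses, rose as a list (adjusted p = 7.93e-09, and 0.613 with an estimated correlation). 29 of 29 members lay above 0, with a median of 1.28, or 0.85 without sheep 209 (adjusted p = 2.38e-06). The kinase EIF2AK2 stood at 572 ± 42.1 against 2162 ± 2677, MX2 at 24.8 ± 7.64 against 3807 ± 7649 and HERC6 at 37.0 ± 2.84 against 815 ± 1492. Sheep 315 had a list mean of 11.35 where the libraries other than sheep 209 and 315 had 6.17 to 7.19. Without both animals the median was 0.069 (adjusted p = 0.422). Hypoxia and glycolysis genes rose as a list (adjusted p = 1.75e-06, and 0.464 with an estimated correlation). 26 of 33 members lay above 0, with a median of 0.39, or 0.23 without sheep 209 (adjusted p = 2.38e-06). Hexokinase HK2 was at 534 ± 136 against 956 ± 216 (0.84 ± 0.22), GPI at 2139 ± 315 against 2877 ± 285 (0.43 ± 0.13) and PGK1 at 2521 ± 514 against 3838 ± 775 (0.60 ± 0.19). Oxidative phosphorylation genes rose as a list (adjusted p = 6.94e-05, and 0.649 with an estimated correlation). 37 of 42 members lay above 0, with a median of 0.12, or 0.18 without sheep 209 (adjusted p = 2.70e-08). Changes were 0.31 ± 0.13 for ATP5MC3 and 0.25 ± 0.13 for ATP5F1C, subunits of ATP synthase, and 0.28 ± 0.13 for the complex I subunit NDUFA9.

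Unfolded protein and heat shock genes rose as a list (adjusted p = 0.000339, and 0.613 with an estimated correlation). 21 of 29 members lay above 0, with a median of 0.29, or 0.17 without sheep 209 (adjusted p = 0.0128). The chaperones HSPA5 and HSP90AA1 stood at 11218 ± 2717 against 15908 ± 4133 and 28652 ± 2433 against 39261 ± 7234. Genes of ovulation and luteinization rose as a list (adjusted p = 0.00761, and 0.613 with an estimated correlation). 20 of 25 members lay above 0, with a median of 0.32, or 0.18 without sheep 209 (adjusted p = 0.0409). TNFAIP6, which organizes the matrix of the cumulus, was at 104 ± 147 against 1321 ± 2099.9 (3.86 ± 1.97) and EREG, an EGF-like factor induced by luteinizing hormone, at 11.3 ± 11.8 against 499.9 ± 949. Their means in prenatal T animals without sheep 209 were 389.8 ± 324 and 78.9 ± 136. Immediate early genes rose as a list (adjusted p = 0.000349, and 0.700 with an estimated correlation). 23 of 28 members lay above 0, with a median of 0.83, or 0.28 without sheep 209 (adjusted p = 0.176). The phosphatase DUSP1 was at 438 ± 85.2 against 1465 ± 1618 and JUNB at 558 ± 287 against 3610.0 ± 5572, or 748 ± 243 and 1135 ± 745 in prenatal T animals without sheep 209. Cytokine and NF-kappaB genes rose as a list (adjusted p = 0.00556, and 0.751 with an estimated correlation). 22 of 25 members lay above 0, with a median of 0.77, or 0.022 without sheep 209 (adjusted p = 0.783). SOCS3, a feedback inhibitor of cytokine signalling, was at 397 ± 336 against 2199 ± 3572 and IL1R1 at 157 ± 127 against 1012 ± 1718, or 610.3 ± 422 and 247 ± 172 in prenatal T animals without sheep 209.

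Theca markers fell as a list (adjusted p = 1.82e-05, and 0.486 with an estimated correlation). 16 of 20 members lay below 0, with a median of -0.59, or -0.50 without sheep 209 (adjusted p = 2.53e-06). The collagens COL1A1 and COL1A2 stood at 25085 ± 8402 against 8938 ± 4148 and 14265 ± 4759 against 5673 ± 1879.6, NR2F1 at 126 ± 23.7 against 66.9 ± 25.8 and GLI1, the hedgehog effector, at 62.0 ± 13.9 against 30.7 ± 12.4. Without sheep 209, COL1A1 (-1.25 ± 0.32) and COL1A2 (-1.25 ± 0.33) passed when adjusted over the list alone. Extracellular matrix genes fell as a list (adjusted p = 0.0137, and 0.718 with an estimated correlation). 26 of 43 members lay below 0, with a median of -0.19, or -0.19 without sheep 209 (adjusted p = 0.00648). LOXL1, a collagen cross-linker, was at 901 ± 354 against 459 ± 128 and the laminin LAMB1 at 14763 ± 5637 against 7962 ± 2081. Hedgehog, Notch and Wnt genes fell as a list (adjusted p = 0.0127, and 0.486 with an estimated correlation). 30 of 44 members lay below 0, with a median of -0.25, or -0.20 without sheep 209 (adjusted p = 0.0128). The Wnt target AXIN2 was at 754 ± 157 against 442 ± 91.7 (-0.77 ± 0.20), TCF7L2 at 2487 ± 276 against 1755 ± 333 (-0.52 ± 0.16) and the Wnt coreceptor LRP5 at 4093 ± 205 against 3253 ± 327 (-0.34 ± 0.11). Chromatin modifiers fell as a list (adjusted p = 0.000587, and 0.574 with an estimated correlation). 38 of 53 members lay below 0, with a median of -0.18, or -0.14 without sheep 209 (adjusted p = 7.33e-05). The DNA methyltransferase DNMT3A was at 2849.8 ± 114 against 2176 ± 323 (-0.40 ± 0.13), the acetyltransferase KAT2B at 1303 ± 173 against 968 ± 145 (-0.43 ± 0.15) and the demethylase KDM5B at 5316 ± 405 against 4214 ± 639 (-0.34 ± 0.14). Ribosomal proteins fell as a list (adjusted p = 0.00776, and 0.801 with an estimated correlation). 56 of 64 members lay below 0, with a median of -0.13, or 0.0068 without sheep 209 (adjusted p = 0.592). Changes were -0.49 ± 0.30 for RPS3 and -0.33 ± 0.25 for RPL22, and -0.30 ± 0.25 and -0.20 ± 0.22 without sheep 209.

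When sheep 209 was left out, camera called 4 further lists up and 1 down. Cell cycle genes had 45 of 49 members above 0 and a median of 0.31 (adjusted p = 2.84e-06, and 0.633 with an estimated correlation), against 0.033 with all libraries (adjusted p = 0.559). Granulosa markers had 17 of 18 members above 0 and a median of 0.33 (adjusted p = 0.00517, and 0.611 with an estimated correlation), against -0.93 with all libraries (adjusted p = 0.161). Cholesterol synthesis genes had 19 of 22 members above 0 and a median of 0.18 (adjusted p = 0.0350, and 0.799 with an estimated correlation), against 0.047 with all libraries (adjusted p = 0.252). Steroidogenesis genes had 15 of 21 members above 0 and a median of 0.38 (adjusted p = 0.0494, and 0.611 with an estimated correlation), against -0.16 with all libraries (adjusted p = 0.559). Insulin and IGF genes, the list down, had 13 of 40 members above 0 and a median of -0.12 (adjusted p = 0.0276, and 0.611 with an estimated correlation), against -0.086 with all libraries (adjusted p = 0.220). The remaining lists were called neither with nor without sheep 209. TGF-beta, BMP and activin genes had 14 of 38 members above 0 and a median of -0.14 (adjusted p = 0.485), or 0.090 without sheep 209 (adjusted p = 0.763). Apoptosis and atresia genes had 18 of 27 members above 0 and a median of 0.11 (adjusted p = 0.134), or -0.0037 without sheep 209 (adjusted p = 0.697). Endothelium had 5 of 23 members above 0 and a median of -0.19 (adjusted p = 0.252), or -0.21 without sheep 209 (adjusted p = 0.317). Immune cells had 15 of 20 members above 0 and a median of 0.24 (adjusted p = 0.304), or -0.55 without sheep 209 (adjusted p = 0.106). Oocyte genes had 1 of 11 members above 0 and a median of -0.59 (adjusted p = 0.256), or -0.13 without sheep 209 (adjusted p = 0.938). Ovarian surface epithelium had 7 of 9 members above 0 and a median of 0.72 (adjusted p = 0.142), or 0.33 without sheep 209 (adjusted p = 0.317). Sex steroid and gonadotropin receptors had 6 of 20 members above 0 and a median of -0.10 (adjusted p = 0.315), or -0.054 without sheep 209 (adjusted p = 0.394). Smooth muscle and pericytes had 6 of 17 members above 0 and a median of -0.027 (adjusted p = 0.627), or -0.26 without sheep 209 (adjusted p = 0.618). With all libraries the test of the steroidogenesis list pointed up while its median and mean (-0.26) were negative, and that of smooth muscle and pericytes pointed down with a mean of 0.079.

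Among 18 fixed genes of follicular function, INSR, the insulin receptor, stood in granulosa cells at 9355 ± 1434 against 6571 ± 1729 (-0.54 ± 0.22) and AMHR2, the receptor of AMH, at 146 ± 13.2 against 100.1 ± 41.1 (-0.67 ± 0.38). Changes are given for all but 1 of the fixed genes. In granulosa cells the log2 changes with all libraries, and without sheep 209 in parentheses, were ESR1 -0.21 ± 0.25 (-0.038), ESR2 -1.09 ± 1.39 (0.29) and PGR 0.031 ± 0.29 (0.040) for the steroid receptors. They were FSHR -2.16 ± 2.20 (0.038) and LHCGR -1.71 ± 1.87 (0.049) for the gonadotropin receptors and AMH -2.24 ± 2.45 (0.21), INHA -1.80 ± 2.25 (0.41) and INHBA -0.28 ± 1.48 (0.84) for the hormones of the TGF-beta family. For aromatase and the other steroidogenic genes they were CYP19 -0.95 ± 2.13 (0.77), CYP17A1 -1.94 ± 1.46 (-0.50), STAR -0.25 ± 0.79 (-0.18) and CYP11A1 -1.38 ± 2.17 (0.70). The rest were INSL3 -2.95 ± 1.84 (-1.13), FOXL2 -1.46 ± 1.49 (0.016) and IGF1 -0.42 ± 0.69 (-0.90). AMH stood at 4440.3 ± 1691 in controls and 4056 ± 2783 in prenatal T animals, or 5071 ± 1864 without sheep 209. The sign of the change of AMH, ESR2, FSHR, LHCGR, INHA, CYP11A1 and FOXL2 rests on sheep 209, and that of INHBA and CYP19 turns without sheep 209 and also without control sheep 244. Two-sided exact permutation tests over these genes in both layers (36 tests) gave 0 with an adjusted p under 0.05. An exact p under 0.05 was given by 2, INSR in granulosa cells (exact p = 0.0476, adjusted p = 0.857) and IGF1 in theca cells (exact p = 0.0159, adjusted p = 0.571). Without sheep 209, 0 of 36 passed (smallest adjusted p = 0.490).

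**Figure D1:**
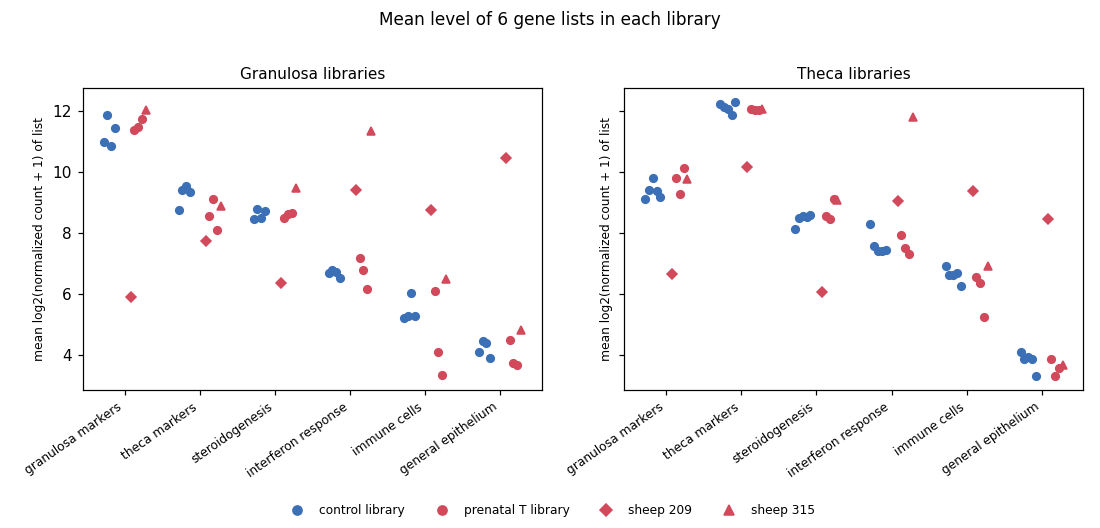
Mean log2 value of 6 gene lists (vertical axis) in each granulosa and theca library, by group, with sheep 209 as diamonds and sheep 315 as triangles. Sheep 209 lies at 5.91 for granulosa markers in granulosa cells where the other libraries lie at 10.85 to 12.03, and sheep 315 lies at 11.35 for the interferon response.

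In theca cells DTX4, a ubiquitin ligase of the Notch pathway, had the smallest p, at 879 ± 146 in controls and 448 ± 83.5 in prenatal T animals (-0.98 ± 0.17). LPAR6, a receptor of lysophosphatidic acid, stood at 99.8 ± 15.9 against 209 ± 40.7 (1.05 ± 0.20), and TTN, the giant protein titin, at 137 ± 52.8 against 40.4 ± 9.85 (-1.64 ± 0.37). The RNA-binding protein MEX3D was at 2193 ± 192 against 1555 ± 137 (-0.50 ± 0.10), RGL1, an exchange factor of Ral, at 1601 ± 177 against 1109 ± 105 (-0.53 ± 0.11) and the histone deacetylase HDAC5 at 2823 ± 208 against 2043 ± 282 (-0.47 ± 0.11). Levels were higher in prenatal T animals for NMD3, an export factor of the large ribosomal subunit (0.78 ± 0.17), the prefoldin subunit VBP1 (0.61 ± 0.14), SUCO (0.52 ± 0.12) and SAR1B, a GTPase of secretory vesicles (0.69 ± 0.16). All 5 prenatal T libraries lay on the same side of all 5 controls for each of these 10 genes except SAR1B, where 4 did.

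The limma test called 0 of 15492 genes in theca cells (smallest adjusted p = 0.644), with 1192 at an unadjusted p under 0.05. edgeR called 0 (1561 at an unadjusted p under 0.05), and DESeq2 called 9, 4 up and 5 down. These were LPAR6 (adjusted p = 0.00181), VBP1 (0.0477), DTX4 (0.00194), TTN (0.00949), MEX3D (0.0230), RGL1 (0.0230) and, chosen after their values were seen, CEPT1, MANEA and ZNF574. Without sheep 209 limma called 0 (1854 at an unadjusted p under 0.05), edgeR 0 and DESeq2 57 (37 up, 20 down). Genes that entered the 10 of smallest p were then RET, the receptor tyrosine kinase of the GDNF family (-1.69 ± 0.30, against -0.88 ± 0.76 with all libraries) and ENPEP, the aminopeptidase that cleaves angiotensin II (0.98 ± 0.20, against 0.22 ± 0.68). Others were NOC3L (0.59 ± 0.12), the mitochondrial ribosomal protein MRPL1 (0.72 ± 0.14), the calcium channel subunit CACNB3 (-0.71 ± 0.14), the centrin CETN3 (0.50 ± 0.10) and the kinase ITPKA (-1.01 ± 0.21).

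**Figure D2:**
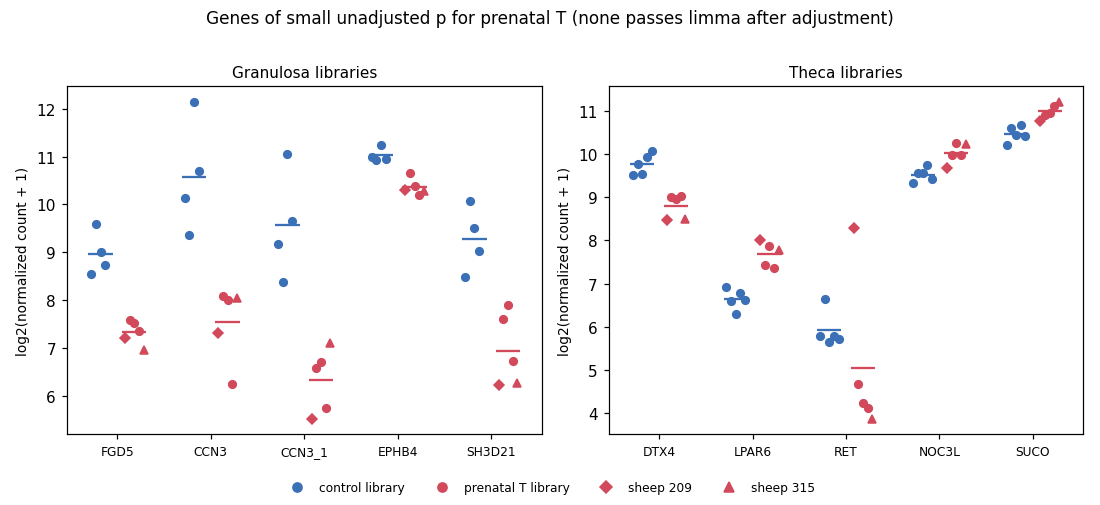
Levels of 10 genes, as log2 of the normalized count plus 1 (vertical axis), in each control and prenatal T library, with bars at the group means. FGD5, CCN3, CCN3_1, EPHB4 and SH3D21 are shown in granulosa cells and DTX4, LPAR6, RET, NOC3L and SUCO in theca cells, where DTX4 has a mean level of 879 ± 146 against 448 ± 83.5.

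In theca cells camera called 13 of 24 lists, 8 up and 5 down, and 11 without sheep 209. With an estimated correlation 0 were called (smallest adjusted p = 0.894, and 0.839 without sheep 209). By fry 0 were called (smallest adjusted p = 0.575), and in each list 0 members passed by limma over all genes or adjusted over the list alone. The interferon response genes rose as a list (adjusted p = 1.55e-06, and 0.894 with an estimated correlation). 30 of 30 members lay above 0, with a median of 1.02, or 0.93 without sheep 209 (adjusted p = 2.41e-05). IFIT3 stood at 127 ± 59.7 against 1538 ± 2741, IFI44L at 41.7 ± 14.3 against 342 ± 585 and PARP14 at 1052 ± 161 against 2661 ± 3004. The list mean of sheep 315 was 11.81 against 7.30 to 8.29 in the libraries other than sheep 209 and 315. Leaving out both animals gave a median of 0.047 (adjusted p = 0.794). Cholesterol synthesis genes rose as a list (adjusted p = 0.00995, and 0.894 with an estimated correlation). 19 of 22 members lay above 0, with a median of 0.25, or 0.38 without sheep 209 (adjusted p = 1.83e-05). The sterol carrier STARD4 was at 168 ± 34.8 against 310.2 ± 93.0 (0.84 ± 0.26), SC5D at 428 ± 13.1 against 604 ± 171 (0.45 ± 0.19) and the LDL receptor at 1140.3 ± 352 against 2125 ± 1062 (0.76 ± 0.38). The ovulation and luteinization genes rose as a list (adjusted p = 0.00221, and 0.894 with an estimated correlation). 20 of 26 members lay above 0, with a median of 0.45, or 0.20 without sheep 209 (adjusted p = 0.0422). TNFAIP6 was at 20.6 ± 20.5 against 735 ± 1352, or 131 ± 83.1 in prenatal T animals without sheep 209 (2.78 ± 0.74).

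The unfolded protein and heat shock genes rose as a list (adjusted p = 0.000215, and 0.894 with an estimated correlation). 26 of 30 members lay above 0, with a median of 0.27, or 0.12 without sheep 209 (adjusted p = 0.0909). HSP90B1 was at 17381 ± 2279 against 25747 ± 11270.5 and DNAJB9 at 287 ± 96.7 against 514 ± 279. The immediate early genes rose as a list (adjusted p = 0.000464, and 0.894 with an estimated correlation). 27 of 28 members lay above 0, with a median of 0.68, or 0.014 without sheep 209 (adjusted p = 0.738). FOS was at 262 ± 62.9 against 859.6 ± 1014 and the nuclear receptor NR4A1 at 156 ± 40.2 against 754 ± 880.0, or 407 ± 80.4 and 389.9 ± 384 in prenatal T animals without sheep 209. The hypoxia and glycolysis genes rose as a list (adjusted p = 0.0122, and 0.894 with an estimated correlation). 26 of 33 members lay above 0, with a median of 0.31, or 0.029 without sheep 209 (adjusted p = 0.847). The oxygen-regulated factor HIF1A was at 4562 ± 471 against 9287 ± 6172. The cytokine and NF-kappaB genes rose as a list (adjusted p = 0.00801, and 0.894 with an estimated correlation). 22 of 27 members lay above 0, with a median of 0.52, or 0.0071 without sheep 209 (adjusted p = 0.864). IL1A was at 35.2 ± 17.9 against 306 ± 579, or 47.4 ± 10.0 in prenatal T animals without sheep 209. Smooth muscle and pericyte genes rose as a list (adjusted p = 0.0174, and 0.894 with an estimated correlation). 15 of 18 members lay above 0, with a median of 0.26, or 0.10 without sheep 209 (adjusted p = 0.435). RGS5, a marker of pericytes, was at 2206 ± 596 against 3099 ± 877 (0.49 ± 0.23) and the actin ACTG2 at 5952 ± 1497 against 7918 ± 2379 (0.40 ± 0.23).

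The chromatin modifiers fell as a list (adjusted p = 0.000215, and 0.894 with an estimated correlation). 43 of 53 members lay below 0, with a median of -0.15, or -0.17 without sheep 209 (adjusted p = 3.22e-05). The DNA methyltransferase DNMT3B was at 159 ± 29.6 against 103 ± 17.4 (-0.62 ± 0.20) and the histone methyltransferase EHMT2 at 2090.4 ± 135 against 1655 ± 260.0 (-0.35 ± 0.12). The hedgehog, Notch and Wnt genes fell as a list (adjusted p = 0.0314, and 0.894 with an estimated correlation). 28 of 45 members lay below 0, with a median of -0.27, or -0.13 without sheep 209 (adjusted p = 0.0422). SUFU, which restrains hedgehog signalling, was at 928 ± 109 against 669.9 ± 148 (-0.49 ± 0.17), the receptor NOTCH3 at 4582 ± 828 against 3397 ± 585 (-0.43 ± 0.16) and GLI3 at 1298 ± 189 against 889.9 ± 251 (-0.59 ± 0.22). The theca markers fell as a list (adjusted p = 0.0314, and 0.894 with an estimated correlation). 15 of 20 members lay below 0, with a median of -0.33, or -0.14 without sheep 209 (adjusted p = 0.435). GLI2 was at 1429 ± 388 against 993 ± 345 and the proteoglycan DCN, to the other side, at 15304 ± 2273 against 19364 ± 3775. Cell cycle genes fell as a list (adjusted p = 0.0314, and 0.923 with an estimated correlation). 40 of 49 members lay below 0, with a median of -0.27, or 0.013 without sheep 209 (adjusted p = 0.847). FOXM1 was at 278 ± 124 against 178 ± 81.8. The ribosomal proteins fell as a list (adjusted p = 0.0224, and 0.923 with an estimated correlation). 47 of 64 members lay below 0, with a median of -0.14, or 0.12 without sheep 209 (adjusted p = 0.000806). The direction of this list turned without sheep 209, with 43 of 64 members above 0 (adjusted p = 0.839 with an estimated correlation). RPS16 was at 11417 ± 1525 against 9391 ± 2774.

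In theca cells 3 lists were called up, and 2 down, only when sheep 209 was left out. Steroidogenesis genes of theca cells had 16 of 21 members above 0 and a median of 0.28 (adjusted p = 0.00770, and 0.839 with an estimated correlation), against -0.0063 with all libraries (adjusted p = 0.624). Granulosa markers in theca cells had 14 of 17 members above 0 and a median of 0.27 (adjusted p = 0.0258, and 0.839 with an estimated correlation), against -0.27 with all libraries (adjusted p = 0.633). Oxidative phosphorylation genes had 31 of 42 members above 0 and a median of 0.15 (adjusted p = 0.000806, and 0.839 with an estimated correlation), against 0.034 with all libraries (adjusted p = 0.370). Of the lists down, immune cells had 3 of 25 members above 0 and a median of -0.26 (adjusted p = 0.0105, and 0.839 with an estimated correlation), against 0.26 with all libraries (adjusted p = 0.624). Extracellular matrix genes had 13 of 44 members above 0 and a median of -0.18 (adjusted p = 0.0258, and 0.839 with an estimated correlation), against 0.011 with all libraries (adjusted p = 0.854). Then VCAN, a matrix proteoglycan (log2 change 0.69 ± 0.15), and GJA1, the gap junction protein connexin 43 (0.67 ± 0.16), passed when adjusted over the list alone, and both are named here after their values were seen. The other lists of theca cells were not called. TGF-beta, BMP and activin genes had 17 of 38 members above 0 and a median of -0.030 (adjusted p = 0.633), or -0.025 without sheep 209 (adjusted p = 0.847). Apoptosis and atresia genes had 15 of 28 members above 0 and a median of 0.033 (adjusted p = 0.618), or 0.00048 without sheep 209 (adjusted p = 0.847). Endothelium had 11 of 23 members above 0 and a median of -0.075 (adjusted p = 0.854), or -0.033 without sheep 209 (adjusted p = 0.738). Insulin and IGF genes had 14 of 39 members above 0 and a median of -0.12 (adjusted p = 0.375), or -0.14 without sheep 209 (adjusted p = 0.0718). Ovarian surface epithelium had 7 of 9 members above 0 and a median of 0.62 (adjusted p = 0.370), or -0.0012 without sheep 209 (adjusted p = 0.847). Sex steroid and gonadotropin receptors had 11 of 20 members above 0 and a median of 0.032 (adjusted p = 0.876), or 0.083 without sheep 209 (adjusted p = 0.738). The test pointed down with a positive mean for endothelium (0.056) and with a positive median and mean for the extracellular matrix list (0.011 and 0.068). It pointed down with a positive median and a negative mean (-0.19) for sex steroid and gonadotropin receptors, and pointed up with a negative median and mean (-0.0063 and -0.18) for steroidogenesis. Without sheep 209 the signs of test, median and mean differed for apoptosis and ribosomal proteins in granulosa cells, for hypoxia and glycolysis in theca cells and for cytokine genes in both, none of them called then. The oocyte list had too few members past the filter in theca cells and was not tested there.

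Of the fixed genes in theca cells, IGF1, a growth factor of the follicle wall, had the smallest p, at 1319.5 ± 302 in controls and 3196 ± 2198 in prenatal T animals (1.10 ± 0.34), with 4 of 5 prenatal T libraries above all controls. Without sheep 209 its change was 0.76 ± 0.19 (exact permutation p = 0.0238, adjusted p = 0.490), and DESeq2 called it then (adjusted p = 0.0294). The log2 changes, and those without sheep 209 in parentheses, were ESR1 0.49 ± 0.49 (-0.052), ESR2 -1.44 ± 1.12 (-0.16) and PGR 0.26 ± 0.22 (0.22) for the steroid receptors. They were FSHR -1.22 ± 1.55 (0.49) and LHCGR -1.59 ± 1.98 (0.67) for the gonadotropin receptors and CYP17A1 -1.39 ± 1.82 (0.69), CYP11A1 -1.65 ± 2.04 (0.69), STAR 0.25 ± 0.60 (0.63) and CYP19 0.22 ± 1.51 (1.33) for the steroidogenic genes. The others were AMH -1.34 ± 1.73 (0.62), AMHR2 -0.31 ± 0.38 (-0.085), INHA -1.30 ± 1.53 (0.41) and INHBA 0.77 ± 0.52 (0.66), with INSL3 -2.57 ± 2.07 (-0.22), FOXL2 -0.84 ± 0.78 (0.035) and INSR -0.31 ± 0.19 (-0.23). CYP17A1 stood at 845 ± 205 in controls and 1165 ± 922 in prenatal T animals, or 1457 ± 753 without sheep 209, and LHCGR, the receptor of luteinizing hormone, at 1638 ± 441 against 2167 ± 1632, or 2708 ± 1263. The sign of the change of CYP17A1, CYP11A1, LHCGR, FSHR, AMH, INHA, ESR1 and FOXL2 rests on sheep 209.

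The difference between the prenatal T effects of granulosa and theca cells asks which genes respond by layer. C1QTNF3, a secreted protein of the C1q and TNF family, had the smallest p, with a difference of -1.60 ± 0.25 from levels of 366 ± 108 against 168 ± 64.7 in granulosa and 2255 ± 429 against 3124 ± 1374 in theca cells. FGD5 differed by -1.31 ± 0.24, from 519 ± 176 against 161 ± 27.1 in granulosa and 806 ± 128 against 606 ± 93.1 in theca cells. The difference was -1.19 ± 0.23 for MYLK, the myosin light chain kinase of smooth muscle, -0.93 ± 0.17 for the integrin ITGA8 and -0.62 ± 0.12 for SERINC1. It was positive for the scavenger receptor SCARA3 (0.47 ± 0.085), the clock repressor BHLHE41 (0.87 ± 0.18), the collagenase MMP13 (2.12 ± 0.43), the Nogo receptor RTN4R (2.24 ± 0.51) and OXT, the hormone oxytocin (2.56 ± 0.53). For OXT sheep 315 stood at 2011 in granulosa cells and the other libraries at 2.29 to 58.1.

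By limma 0 of 16269 genes passed (smallest adjusted p = 0.663, 758 at an unadjusted p under 0.05). edgeR called 0 (794 at an unadjusted p under 0.05) and DESeq2 16. The 3 up were SCARA3 (adjusted p = 0.000739), BHLHE41 (0.0275) and OXT (0.0275), and the 13 down included C1QTNF3 (0.000209), FGD5 (0.00575) and MYLK (0.0124). Without sheep 209 limma called 0 (smallest adjusted p = 0.123, 1326 at an unadjusted p under 0.05), edgeR 0 and DESeq2 30 (6 up, 24 down). CTTNBP2 (-1.54 ± 0.20, against -0.91 ± 0.62 with all libraries), the Wnt antagonist FRZB (-1.64 ± 0.22), LDLRAD4 (-0.97 ± 0.17), the ubiquitin ligase adaptor KLHL3 (1.34 ± 0.23, against 0.70 ± 0.64) and PHLDA1 (0.63 ± 0.14) then entered the 5 of smallest p in their direction. Several of the genes with a negative difference are abundant in theca cells. MYLK stood at 24448 ± 6527 in control theca and 1628 ± 296 in control granulosa libraries. The estimated share of theca RNA in granulosa libraries, given above, was lower in value in prenatal T animals without sheep 209. Whether a list differed between layers was not tested.

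Granulosa and theca cells were compared within animals. IHH, the hedgehog ligand of granulosa cells, was higher in granulosa cells by 3.16 ± 0.21 (3543 ± 1869 in control granulosa and 279 ± 137 in control theca). So were the neuronal pentraxin NPTX2 (2.97 ± 0.22), ACSBG1, an acyl-CoA synthetase (2.91 ± 0.36), the GDNF family receptor GFRA3 (2.73 ± 0.23), the proton pump subunit ATP6V1C2 (2.61 ± 0.13) and aromatase, listed as CYP19 (2.83 ± 0.43). ESRP1, an epithelial splicing regulator, was at 36.4 ± 24.6 in control granulosa and listed at 0 in control theca libraries. ESRP1, ELF3 (2.91 ± 0.36), the anion exchanger SLC26A4 (2.84 ± 0.19) and the collagenase MMP1 (2.61 ± 0.39) had high levels in the granulosa library of sheep 209, at 2198, 5768, 2969.9 and 10930.2. Without it the changes of the last 3 were 3.03 ± 0.44, 2.82 ± 0.21 and 2.83 ± 0.38. When sheep 209 was left out, SCN10A, NPTX1, SLC35G1, the proteoglycan SRGN (2.69 ± 0.12) and the hexokinase HK2 (2.68 ± 0.15) took places among the 10 largest.

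Higher in theca cells were C1QTNF7 (-5.63 ± 0.42), the opioid precursor PENK (-5.61 ± 0.53), the chemokine CCL21 (-5.39 ± 0.57) and SBSPON (-5.34 ± 0.53). So were the adenylyl cyclase ADCY8 (-5.22 ± 0.38), DGKB (-5.21 ± 0.43), SORCS2 (-5.19 ± 0.46), the transcription factor TCF23 (-5.19 ± 0.31), VIPR2, a receptor of vasoactive intestinal peptide (-5.16 ± 0.52), and desmin, DES, of smooth muscle (-5.04 ± 0.24). Without sheep 209, LHX9 (-5.67 ± 0.30) and HSPB8 (-5.55 ± 0.30) joined them. Among the fixed genes, AMH (2.33 ± 0.25), FSHR (2.29 ± 0.29), INHA (2.30 ± 0.28), AMHR2 (1.47 ± 0.19) and INSR (0.49 ± 0.082) were higher in granulosa cells. LHCGR (-2.00 ± 0.42), CYP17A1 (-2.33 ± 0.37), STAR (-1.24 ± 0.34), CYP11A1 (-1.24 ± 0.35), INSL3 (-2.19 ± 0.33), PGR (-1.88 ± 0.090) and IGF1 (-4.17 ± 0.20) were higher in theca cells. ESR1 (0.25 ± 0.35), ESR2 (0.14 ± 0.11), INHBA (1.32 ± 0.64) and FOXL2 (0.19 ± 0.30) did not pass, and without sheep 209 ESR1 (0.61 ± 0.082), INHBA (1.94 ± 0.26) and FOXL2 (0.49 ± 0.10) did. In all, limma called 9124 of 16269 genes, 4648 higher in granulosa and 4476 higher in theca cells, and 10132 without sheep 209.

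By camera 17 of 25 lists differed between the layers, 8 higher in granulosa and 9 higher in theca cells. With an estimated correlation 0 did, and fry called 19. Over all lists 511 members passed when adjusted over the list alone. Granulosa markers were higher in granulosa cells as a list (adjusted p = 3.53e-05, and 0.433 with an estimated correlation). 14 of 18 members passed this way, 14 adjusted over the list alone, with a median of 1.88, or 2.18 without sheep 209 (adjusted p = 1.69e-08). Besides AMH and INHA these held the protease inhibitor SERPINE2 (1.93 ± 0.20) and the estradiol-forming enzyme HSD17B1 (1.92 ± 0.21). Cell cycle genes were higher in granulosa cells as a list (adjusted p = 1.42e-12, and 0.433 with an estimated correlation). 43 of 49 members passed this way, 43 adjusted over the list alone, with a median of 0.95, or 0.95 without sheep 209 (adjusted p = 7.03e-11). Examples were TOP2A (1.21 ± 0.10), PLK1 (1.06 ± 0.083) and TTK (1.23 ± 0.094). Hypoxia and glycolysis genes were higher in granulosa cells as a list (adjusted p = 1.07e-05, and 0.433 with an estimated correlation). 24 of 33 members passed this way, 24 adjusted over the list alone, with a median of 0.84, or 0.97 without sheep 209 (adjusted p = 9.49e-08). Examples were the glycolytic enzymes LDHA (1.46 ± 0.16), ENO1 (1.16 ± 0.12) and PFKL (0.93 ± 0.085). Cholesterol synthesis genes were higher in granulosa cells as a list (adjusted p = 1.63e-05, and 0.433 with an estimated correlation). 17 of 22 members passed this way, 18 adjusted over the list alone, with a median of 0.62, or 0.52 without sheep 209 (adjusted p = 0.000220). They included the enzymes MSMO1 (1.54 ± 0.10), FDFT1 (0.65 ± 0.080) and DHCR7 (1.24 ± 0.14). Oxidative phosphorylation genes were higher in granulosa cells as a list (adjusted p = 0.00441, and 0.433 with an estimated correlation). 19 of 42 members passed this way, 18 adjusted over the list alone, with a median of 0.13, or 0.11 without sheep 209 (adjusted p = 0.0314). SDHA (0.60 ± 0.059) and NDUFS4 (0.95 ± 0.10) of the respiratory chain were among them. Unfolded protein and heat shock genes were higher in granulosa cells as a list (adjusted p = 0.0111, and 0.433 with an estimated correlation). 15 of 30 members passed this way, 15 adjusted over the list alone, with a median of 0.24, or 0.28 without sheep 209 (adjusted p = 0.00727). CHAC1 (2.37 ± 0.20) and HERPUD1 (1.76 ± 0.21) were examples. Chromatin modifiers were higher in granulosa cells as a list (adjusted p = 0.0294, and 0.433 with an estimated correlation). 21 of 53 members passed this way, 21 adjusted over the list alone, with a median of 0.10, or 0.13 without sheep 209 (adjusted p = 0.0334). EZH2 (0.64 ± 0.078) and HDAC2 (0.42 ± 0.047) were higher in granulosa, KAT2B (-0.93 ± 0.10) and TET1 (-0.96 ± 0.12) in theca cells. Oocyte genes were higher in granulosa libraries as a list, with 10 of 11 members passing, 10 adjusted over the list alone (adjusted p = 0.00281, and adjusted p = 0.433 with an estimated correlation), or adjusted p = 0.00264 without sheep 209. The zona protein ZP3 was at 76.7 ± 71.4 in control granulosa and 0.403 ± 0.555 in control theca, and MOS, a kinase of oocyte maturation, at 51.4 ± 43.4 and 0 in all theca libraries, so no median is given.

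Theca markers were lower in granulosa cells as a list (adjusted p = 2.02e-13, and 0.217 with an estimated correlation). 20 of 20 members passed this way, 20 adjusted over the list alone, with a median of -2.97, or -3.02 without sheep 209 (adjusted p = 1.27e-11). COL1A1 (-4.39 ± 0.16), COL1A2 (-4.29 ± 0.16), GLI1 (-3.31 ± 0.15) and the actin ACTA2 (-5.04 ± 0.14) were examples. Smooth muscle and pericyte genes were lower in granulosa cells as a list (adjusted p = 1.14e-10, and 0.0814 with an estimated correlation). 17 of 18 members passed this way, 17 adjusted over the list alone, with a median of -2.60, or -2.63 without sheep 209 (adjusted p = 1.79e-09). MYLK was at -4.35 ± 0.12 and LMOD1 at -4.41 ± 0.24. Endothelium genes were lower in granulosa cells as a list (adjusted p = 1.17e-10, and 0.218 with an estimated correlation). 20 of 23 members passed this way, 20 adjusted over the list alone, with a median of -2.37, or -2.34 without sheep 209 (adjusted p = 2.15e-08). These included von Willebrand factor, VWF (-2.85 ± 0.17), CLDN5 (-2.77 ± 0.14) and ENG (-2.58 ± 0.13). Extracellular matrix genes were lower in granulosa cells as a list (adjusted p = 6.68e-14, and 0.217 with an estimated correlation). 37 of 44 members passed this way, 37 adjusted over the list alone, with a median of -2.22, or -2.12 without sheep 209 (adjusted p = 1.69e-10). Elastin, ELN, was at -4.08 ± 0.17 and the laminin LAMA4 at -2.36 ± 0.10. Hedgehog, Notch and Wnt genes were lower in granulosa cells as a list (adjusted p = 5.58e-05, and 0.0720 with an estimated correlation). 28 of 46 members passed this way, 28 adjusted over the list alone, with a median of -1.02, or -1.04 without sheep 209 (adjusted p = 0.000190). GLI2 was at -4.00 ± 0.26 and the receptor FZD4 at -2.06 ± 0.12. Immune cell genes were lower in granulosa cells as a list (adjusted p = 0.000145, and 0.433 with an estimated correlation). 18 of 25 members passed this way, 18 adjusted over the list alone, with a median of -1.15, or -1.22 without sheep 209 (adjusted p = 0.000427). The T cell genes CD3E and CD8A were at -2.23 ± 0.32 and -2.42 ± 0.42, and NKG7 at -2.26 ± 0.24. Cytokine and NF-kappaB genes were lower in granulosa cells as a list (adjusted p = 0.000104, and 0.433 with an estimated correlation). 20 of 28 members passed this way, 22 adjusted over the list alone, with a median of -0.59, or -0.64 without sheep 209 (adjusted p = 8.88e-05). The chemokine CXCL12 was at -2.91 ± 0.15 and, to the other side, the receptor IL6R at 1.27 ± 0.17. Interferon response genes were lower in granulosa cells as a list (adjusted p = 0.00281, and 0.482 with an estimated correlation). 15 of 31 members passed this way, 15 adjusted over the list alone, with a median of -0.53, or -0.60 without sheep 209 (adjusted p = 0.000235). IFI6 was at -0.69 ± 0.11 and IFIT1 at -2.25 ± 0.37. Ribosomal proteins were lower in granulosa cells as a list (adjusted p = 0.0159, and 0.813 with an estimated correlation). 12 of 64 members passed this way, 1 adjusted over the list alone, with a median of -0.13, or -0.18 without sheep 209 (adjusted p = 0.000286). Without sheep 209, 39 passed, 38 adjusted over the list alone. RPS24 was at -0.32 ± 0.070.

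Lists that camera did not call between the layers held members that passed in both directions. TGF-beta, BMP and activin genes had 14 members passing higher and 15 lower of 39, or 14 and 15 adjusted over the list alone, with a median of -0.00059 (adjusted p = 0.987). Apoptosis and atresia genes had 7 members passing higher and 7 lower of 28, or 6 and 7 adjusted over the list alone, with a median of -0.0051 (adjusted p = 0.989). Immediate early genes had 5 members passing higher and 7 lower of 28, or 4 and 6 adjusted over the list alone, with a median of -0.19 (adjusted p = 0.538). Insulin and IGF genes had 21 members passing higher and 14 lower of 40, or 21 and 14 adjusted over the list alone, with a median of 0.33 (adjusted p = 0.542). Ovarian surface epithelium had 6 members passing higher and 2 lower of 10, or 6 and 2 adjusted over the list alone, with a median of 1.24 (adjusted p = 0.227). Ovulation and luteinization genes had 10 members passing higher and 10 lower of 27, or 11 and 11 adjusted over the list alone, with a median of 0.033 (adjusted p = 0.989). Sex steroid and gonadotropin receptors had 4 members passing higher and 7 lower of 20, or 4 and 7 adjusted over the list alone, with a median of -0.0081 (adjusted p = 0.670). Steroidogenesis genes had 9 members passing higher and 6 lower of 21, or 10 and 6 adjusted over the list alone, with a median of 0.23 (adjusted p = 0.408). Higher in granulosa cells were the nuclear receptor PPARG (2.18 ± 0.22), the EGF-like factor BTC (1.99 ± 0.23), the orphan receptor NR5A2 (2.20 ± 0.28), CYB5A (0.79 ± 0.088) and the keratin KRT8 (2.11 ± 0.23). So were UPK1B (1.67 ± 0.30), the death factor BCL2L11 (0.80 ± 0.13) and SGK1 (1.04 ± 0.15). Higher in theca cells were the growth factor IGF2 (-2.44 ± 0.10) and the binding proteins IGFBP3 (-2.50 ± 0.30), IGFBP4 (-3.18 ± 0.16) and IGFBP5 (-1.95 ± 0.30). So were the receptor TGFBR2 (-2.22 ± 0.20), ID1 (-1.07 ± 0.092), the protease ADAMTS1 (-2.12 ± 0.18) and KLF2 (-2.25 ± 0.30). The mean differed in sign from the test for the lists of TGF-beta (0.035), apoptosis (-0.14), insulin and IGF (-0.087) and ovulation genes (-0.10), and for apoptosis so did the median. The erythrocyte list was not tested, having too few members past the filter, and its mean log2 value was 1.10 ± 0.23 in control and 1.16 ± 0.12 in prenatal T granulosa and 1.10 ± 0.21 and 0.98 ± 0.11 in theca cells. Of the mitochondrial genes 0 of 26 were matched in the table.

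The prenatal T effects of granulosa and theca cells were compared across genes. Over 16269 genes the log2 changes of both layers correlated at Pearson r = 0.68 and a Spearman correlation of 0.63, and genes are not independent replicates. When the treatment was reassigned over whole animals in every way, the median r was 0.66 (range 0.47 to 0.78). The real r was not larger than reassignment gives (two-sided permutation p = 0.373, and 0.381 for Spearman). Without sheep 209 r was 0.52 (permutation p = 0.405, 126 assignments) and by Spearman 0.48 (permutation p = 0.270).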

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

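The tests of the 3 patterns were chosen only after the result was seen, with the limits for theca cells and for immune cells rewritten once a value had been computed, while the regroupings of samples were planned, apart from those counted by DESeq2 without sheep 209.

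Dixon's ratio, the gap between the most extreme library and its neighbour over the range of the group, passed its limit in 38 of 176 groups of libraries and fixed genes or list means, where 5 percent of groups are passed by chance, and sheep 209 was the library in 31. In granulosa cells of the prenatal T group sheep 209 was lowest for ESR2 (0.910), FSHR (0.866), AMH (0.916), INHA (0.839), CYP17A1 (0.861), CYP11A1 (0.743), INSL3 (0.817) and FOXL2 (0.923), with AMH at a log2 value of 0 where the nearest library had 11.83. It was also lowest there for the lists of granulosa marker (0.895) and sex steroid and gonadotropin receptor (0.902) genes. In theca cells it was lowest for ESR2 (0.904), FSHR (0.797), LHCGR (0.886), AMH (0.871), INHA (0.824), CYP17A1 (0.853), CYP11A1 (0.889), INSL3 (0.890) and FOXL2 (0.942) and highest for ESR1 (0.933). Of the lists in theca cells it was lowest for granulosa marker (0.759), ribosomal protein (0.868), sex steroid and gonadotropin receptor (0.888), steroidogenesis (0.785) and theca marker (0.979) genes and highest for cytokine (0.739), extracellular matrix (0.731), hypoxia and glycolysis (0.911), immediate early (0.781), ovarian surface epithelium (0.913) and unfolded protein and heat shock (0.768) genes. Among the others, control sheep 268 was lowest in granulosa cells for the lists of TGF-beta, BMP and activin (0.858) and immediate early (0.849) genes and control sheep 246 highest for immune cell (0.893) genes. Sheep 210 of the prenatal T group was highest for chromatin modifier (0.858) genes in granulosa cells. In theca cells control sheep 139 was highest for interferon response (0.813) and lowest for steroidogenesis (0.766) genes, and sheep 276 of the prenatal T group was lowest for PGR (0.745).

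Both libraries of sheep 209 had low levels of follicle genes, with a granulosa marker mean of 5.91 in granulosa and a theca marker mean of 10.17 in theca cells, and held genes of other tissue, such as LTF, the lactoferrin of secretions and neutrophils, at 198387 in granulosa cells (5.06 to 45.0 in the others) and the keratin KRT19 at 34370.5, and its mean of a general epithelium list was 10.45 against 3.68 to 4.84. Scaling of the libraries is argued against, because the epithelium list lay 6.50 further above the other libraries than the follicle markers in the layer where this was smaller, and scaling moves all genes alike. An effect shared by the treated animals is argued against too, as 2 of the other 4 prenatal T animals lay above every control in that list and none came near sheep 209. A candidate explanation that stays open is tissue from outside the follicle wall, which microdissection should have removed, with the epithelium list 6.19 above the median of the other granulosa libraries, 31 of 33 genes above every other library, 19 of the 33 at 10 or more in other libraries as well and 4 in another list. An exchange with a sample from outside the study also stays open, because it would leave no partner among these libraries.

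Theca markers, of which all 20 passed the filter in granulosa libraries and COL1A1, COL1A2, GLI1, GLI2 and ACTA2 are also in other lists, were called lower in prenatal T granulosa cells (median -0.50 without sheep 209, 17 of 20 members below 0) by the test with a preset correlation alone (adjusted p = 2.53e-06, and adjusted p = 0.611 with an estimated correlation). A fall in theca cells stays open. List mean changes of -0.070 ± 0.075 there (-0.45 with sheep 209) and -0.60 in granulosa cells were not compared. A candidate explanation is less theca RNA carried over into the prenatal T granulosa libraries, which microdissection of the layers should remove: the 100 genes highest in theca cells outside the list had a median change of -0.62 in granulosa cells, 92 of them lower, where 10000 random sets had a median of -0.065 and a lower bound at percentile 5 of -0.15. Without sheep 209 the list means of endothelium (-0.21, exact permutation p = 0.514) and smooth muscle (-0.032, p = 0.914), also higher in theca cells, fell by less than that of the theca markers (p = 0.0857), and the share of theca RNA was not shown to differ between groups by the exact permutation test (p = 0.143). An effect of prenatal testosterone within granulosa cells (median -0.50) and less theca RNA cannot be told apart, as both lower the same genes in the same libraries.

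The interferon list was called up in both layers with a preset correlation, but not with an estimated one (adjusted p = 0.613 in granulosa and adjusted p = 0.894 in theca cells), and its mean in sheep 315 was 11.35 and 11.81. Without sheep 209, 2 of 4 prenatal T animals lay above every control in granulosa and 1 in theca cells. There control 139 was an outlier. A shared treatment effect stays open, though sheep 276 lay below every control in both layers. More immune cells in theca of sheep 315 are argued against by an immune list mean -0.0017 from the highest other library besides sheep 209. That 1 animal, sheep 315, carries the result stays open, and the median fell from 1.28 to 0.069 in granulosa cells without sheep 209 and 315, while without sheep 315 alone it was 0.57 (adjusted p = 8.96e-05) and in theca cells 0.26 (adjusted p = 0.00786). More immune cells in the granulosa library of sheep 315, whose immune list mean lay 0.39 above the highest other with sheep 209 (8.74) left out, cannot be told apart from a response of the granulosa cells themselves, since immune and granulosa cells both express interferon genes. What raised these genes in sheep 315 was not tested.

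The animals were regrouped at random to see which counts chance can give, the real grouping included in each number. A count of 0 genes by limma is reached by every grouping, so these numbers say nothing about chance in granulosa cells (100 of 100 groupings as large, highest other 104), theca cells (100 of 100, highest other 15) or their difference (100 of 100, highest other 18). Groupings that call 104 genes where the real one calls 0 point to a structure of the samples. Between layers chance can be excluded for the 9124 genes (1 of 100, highest other 2406). For the 17 gene lists at the preset correlation it cannot be (2 of 100, highest other also 17). With an estimated correlation 0 were called (smallest adjusted p = 0.0720). For the 12 lists in granulosa cells (40 of 100, highest other 18) and the 13 in theca cells (37 of 100, highest other 17) chance cannot be excluded. The same holds for DESeq2 without sheep 209, with 32 genes in granulosa (12 of 35, highest other 487, median of the others 11) and 57 in theca cells (4 of 40, highest other 89). What gave the count of 487 was not tested.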

How the results depend on the processing

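Counts and values that other settings changed are given here, and the cause was not tested unless stated. By DESeq2 the counts of called genes moved from 0 to 16 in granulosa cells, 9 in theca cells and 16 for their difference, and without sheep 209 to 32, 57 and 30. With markers of the other layer as a covariate and without sheep 209, DESeq2 called 16 in granulosa and 270 in theca cells. With 1 model of all libraries and a replicate block, 1 gene passed in granulosa cells. Between layers the count moved from 9124 to 5729 with no animal block and 5158 in prenatal T animals only. Called lists moved from 12 in granulosa, 13 in theca cells and 17 between layers to 0 with an estimated correlation, and in granulosa and theca cells to 0 by fry. They moved to 7 in granulosa and 7 in theca cells with markers of the other layer as a covariate and no sheep 209, and to 8 in theca cells without sheep 209 and 315.

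The following log2 changes of named genes in granulosa cells had the sign opposite to the value with the settings of the report. With rescaling to equal totals it was -0.036 for PGR. With quantile normalization it was -0.00034 for PGR. With sample quality weights they were 0.017 for RPS3A, 0.17 for ESR2, 0.068 for INHA, 0.62 for INHBA, 0.11 for CYP19 and 0.49 for CYP11A1. With edgeR on recovered reads they were 0.25 for LHCGR, 0.088 for INHA, 0.15 for INHBA, 0.83 for CYP19, 0.81 for STAR, 0.86 for CYP11A1 and 0.10 for IGF1. With DESeq2 on recovered reads they were 0.23 for LHCGR, 0.075 for INHA, 0.13 for INHBA, 0.83 for CYP11A1 and 0.10 for IGF1. With markers of the other layer as a covariate they were 0.034 for SNAP25, 0.091 for RPS3A, 0.10 for RPS12, 1.23 for ESR2, 1.54 for FSHR, 2.36 for LHCGR, 1.63 for AMH, 2.14 for INHA, 2.19 for INHBA, 2.54 for CYP19, 0.99 for CYP17A1, 0.32 for STAR, 2.75 for CYP11A1, 0.79 for INSL3 and 0.94 for FOXL2.

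The following log2 changes of named genes in theca cells had the sign opposite to the value with the settings of the report. With sample quality weights they were -0.019 for ESR1, 0.43 for FSHR, 0.56 for LHCGR, 0.30 for AMH, 0.076 for AMHR2, 0.29 for INHA, 0.50 for CYP17A1 and 0.53 for CYP11A1. With edgeR on recovered reads they were 0.28 for RET, 0.14 for FSHR, 0.40 for LHCGR, 0.27 for AMH, 0.16 for INHA, -0.32 for CYP19, 0.46 for CYP17A1 and 0.43 for CYP11A1. With DESeq2 on recovered reads they were 0.14 for FSHR, 0.40 for LHCGR, 0.27 for AMH, 0.16 for INHA, -0.32 for CYP19, 0.46 for CYP17A1 and 0.43 for CYP11A1. With the share of genes detected as a covariate they were -0.024 for CYP19 and -0.037 for STAR.

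The following log2 changes of named genes in the layer comparison had the sign opposite to the value with the settings of the report. With control animals only it was -0.053 for ESR2. With prenatal T animals only they were -0.13 for ESR1 and -0.061 for FOXL2.

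When each animal was left out in turn, some signs of changes and directions of list tests turned. The ranges of the log2 changes in granulosa cells were -1.53 to 0.29 for ESR2, -2.88 to 0.038 for FSHR, -2.65 to 0.049 for LHCGR, -3.02 to 0.21 for AMH, -2.60 to 0.41 for INHA, -1.03 to 0.84 for INHBA, -2.23 to 0.77 for CYP19, -2.37 to 0.70 for CYP11A1, -1.92 to 0.016 for FOXL2, -0.15 to 0.22 for PGR, -0.99 to 0.082 for STAR and -0.90 to 0.10 for IGF1. In theca cells they were -0.57 to 1.33 for CYP19, -0.052 to 0.65 for ESR1, -1.87 to 0.49 for FSHR, -2.37 to 0.67 for LHCGR, -2.04 to 0.62 for AMH, -1.98 to 0.41 for INHA, -2.14 to 0.69 for CYP17A1, -2.41 to 0.69 for CYP11A1, -1.09 to 0.035 for FOXL2, -0.069 to 0.98 for ENPEP and -0.22 to 0.63 for STAR. Medians of lists ranged over 0.022 to 0.94 for cytokine and -0.22 to 0.0068 for ribosomal protein genes in granulosa cells and over -0.45 to 0.013 for cell cycle, 0.0071 to 0.84 for cytokine and -0.24 to 0.12 for ribosomal protein genes in theca cells. Leaving out sheep 209 gave an end of most ranges, and by construction it removes the libraries with low follicle markers. The counts ranged from 8012 to 10132 genes between layers, 11 to 14 lists in granulosa cells, 10 to 13 lists in theca cells and 16 to 17 lists between layers, and the other counts stayed at 0.

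Over all settings 6935 values of genes kept their sign and their side of the adjusted p threshold, whatever their size. Another 34 passed the threshold only under the other setting, 42 only under the settings of the report, and 96 had the opposite sign. For lists 509 were the same by this rule, 103 no longer passed and 5 were of opposite direction. Of the counts, 154 were the same or close and 19 moved.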

Other observations

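All tests on the lists of neutrophils and glands and on the genes of sheep 315 were chosen only after the result was seen.

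The granulosa library of sheep 209 held secreted proteins of mucosal glands, PIGR at 119556 (0 to 3.55 in the others), DMBT1 at 76943 (8.82 to 107 in the others) and SPP1 at 181234 (40.5 to 534 in the others), with KRT7 at 21819. A list of reproductive tract glands had a mean of 10.80 in its granulosa and 9.09 in its theca library, against 2.84 to 3.79 and 2.10 to 3.17 in the others, with 12 of 14 genes above every other library. The oviduct glycoprotein OVGP1 stood at 19.6 in its granulosa library. Neutrophil genes were high as well, S100A9 at 33236, CXCL8 at 17001 and the receptor CSF3R at 13359, and the neutrophil list had a mean of 11.04 against 1.39 to 3.54, with 15 of 15 genes above every other library. Of the matched genes, 7 of the neutrophil and 5 of the gland list reached 10 in other libraries, and 4 and 1 are in another list. In its theca library ESR1, the estrogen receptor alpha, had a log2 value of 13.01 where the nearest prenatal T library had 10.40.

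The granulosa library of sheep 315 had the highest level of 6 genes of hormone synthesis and its control among the granulosa libraries, picked by their values. In normalized counts, with the range of the granulosa libraries other than sheep 209 and 315 in parentheses, they were OXT at 2011 (2.29 to 58.1), LHCGR at 1802 (193 to 787), STAR at 1853 (95.1 to 363), CYP11A1 at 5014 (478 to 1949.8), CYP19 at 4069 (43.4 to 1767) and INHA at 38080.4 (7238 to 28936). Its mean of the fixed ovulation and luteinization list was 8.57, against 6.73 to 7.71 in those libraries and 9.74 in sheep 209. The interferon gene MX2 was also highest in it among granulosa libraries, at 17443, and its theca library had 238 for OXT and 18425 for MX2.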
